A study of Brassica juncea with 9 samples.

How the data were processed

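Leaf RNA of *Brassica juncea* (Indian mustard), genotype NDR8501, was profiled on 9 one-colour Cy3 oligonucleotide arrays. Per the labels, plants were raised in hydroponic culture and kept for 4 weeks in control solution, in 50 mM NaCl (salt), or in 50 mM NaCl with 2.5 mM bicarbonate (alkaline salt). Each group had 3 biological replicates, and each array held RNA of a middle, fully expanded leaf taken from a single plant. Groups and replicate numbers came from the sample titles.

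The deposited scanner files hold spot intensity on a linear scale, as made by Agilent Feature Extraction 10.1.1.1 with a 1-colour protocol, per the file headers. The submitters' processing notes name version 10.5.1.1 of the same program instead. The processed intensity is background-subtracted and detrended within each array by that program, per the file headers, and is not normalised between arrays. The scan dates in the headers fall before the growing period that the labels give, and the sources used here do not say why. The deposited value table holds log2 values from the authors, with no statement of how they were made. Its columns matched the quantile-normalised log2 processed intensities of the same arrays with a largest difference of 0.0891, after repeated spots were averaged on the linear scale, so its scale and normalisation are inferred from the values. It was not centred per probe.

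Each array carries 45220 spots, of which 1417 were controls and were left out. The remaining 43803 spots hold 43603 probes for 40632 transcript identifiers. The files do not pair probes with gene names, descriptions or sequences, so probes are reported by their array identifier. The 21 gene lists (361 members) fixed before the data were examined could therefore not be applied, and 0 of them were tested. No gene spot was saturated. The 71 spot values that the scanner software marked as outliers were set to missing.

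Values are log2 processed intensity minus the array's own 75th percentile over all probes. Repeated spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which held for 17798 probes. Group means were fitted to all 9 arrays in 1 model per probe with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and no covariate. The 3 contrasts were tested two-sided, and p-values were adjusted by Benjamini-Hochberg over the tested probes of a contrast. A probe is called changed at an adjusted p under 0.05. Where a probe was well above background on none of a group's 3 arrays, its change is given as a bound. Where only some arrays of a group measured it, the fitted change is given with their number, and its size and rank then rest in part on signals at background. The bound sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the dim probe's own signal and the lowest signal among probes well above background on that array. Figures were drawn with matplotlib 3.10.9.

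Tests, groupings, the rule for naming probes and most alternatives were fixed before the data were examined. The naming rule asked for the called probes with a gene name, a log2 change of at least 1, groups that do not overlap, and the largest rises and falls. As no probe carries a gene name, it was applied to probe identifiers measured above background on at least 1 array of both groups, with at most 2 that rose and 2 that fell per contrast. The added naming of the probes with the smallest p, meant for contrasts with few calls, was left out for the same reason. A probe outside the rule, A_46_P116804, is named because salt raised only 2 probes, and it was chosen after its values were seen. The 2 salt fallers well above background in no salt plant, A_46_P231729 and A_46_P239649, were also named outside the rule, after their values were seen. Their fold changes were not followed through every alternative.

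The 3 slides each held 1 array of every group, and the replicate number equals the slide number, so a slide block and a replicate block are the same fit. The scan order also follows the slides. Alternatives covered the normalisation, background correction, the authors' value table, the filter on dim probes, outlier spots, the arrays in the fit, the moderation, the slide as a fixed or random block, the threshold, averaging per transcript identifier, and leaving out each array. The planned normexp correction on mean spot signals was run on median spot signals, as the files carry no mean signal column.

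The fit was tested on simulated data for salt against control: in 20 draws of 17788 probes with 200 changed, it recovered 19.7% of 2-fold and 67.5% of 4-fold changes, with 4.62% of calls false. Overlaps of contrasts that share arrays were set beside 100 simulated data sets without effects and beside the overlap of independent lists. The number of arrays limits the precision: the median width of a 95% confidence interval was 0.61 on either side of a log2 fold change. Between arrays of a group the median SD of a tested probe was 0.33 on the log2 scale, against 0.11 between the 5 repeated spots of a probe within an array, over 18 tested probes.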

Results

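Transcript levels were measured in leaves of *Brassica juncea* plants grown for 4 weeks in control solution, in 50 mM NaCl, or in 50 mM NaCl with 2.5 mM bicarbonate, the ion that makes saline water alkaline. There were 3 plants per group and 1 array per plant. Between 16799 probes (salt replicate 1) and 22063 probes (salt replicate 2) of 43603 were well above background on an array, or 38.5% to 50.6%. In all, 14476 probes were well above background on all 9 arrays and 19712 on none. Signal levels differed between arrays before scaling. The 75th percentile of processed intensity ran from 417 in salt replicate 2 to 1751 in salt replicate 3, and the net signal of negative control spots from 225 to 1901 in the same arrays.

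The alkaline salt plants stood apart from the other 6 plants. The first principal component carried 49.4% of the variance, with scores of 91.0, 84.7 and 94.4 for alkaline salt replicates 1 to 3, −37.8, −35.3 and −56.0 for the salt plants, and −54.0, −66.2 and −20.6 for the controls. Control and salt plants were not separated: the mean correlation across probes, which are not independent replicates, was 0.917 between control arrays, 0.921 between control and salt arrays, and 0.936 between salt arrays. Between control and alkaline salt arrays it was 0.825. On the second component (11.3% of the variance) control replicate 3 scored 37.7, near the salt plants at 20.0 to 26.1, while control replicates 1 and 2 scored −44.6 and −44.7. Alkaline salt replicates 1 to 3 scored −31.8, 24.9 and −9.4 there, so this component also divided the alkaline salt plants. The median SD of a probe was 0.32 in control, 0.26 in salt and 0.27 in alkaline salt plants.

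**Figure D1:**
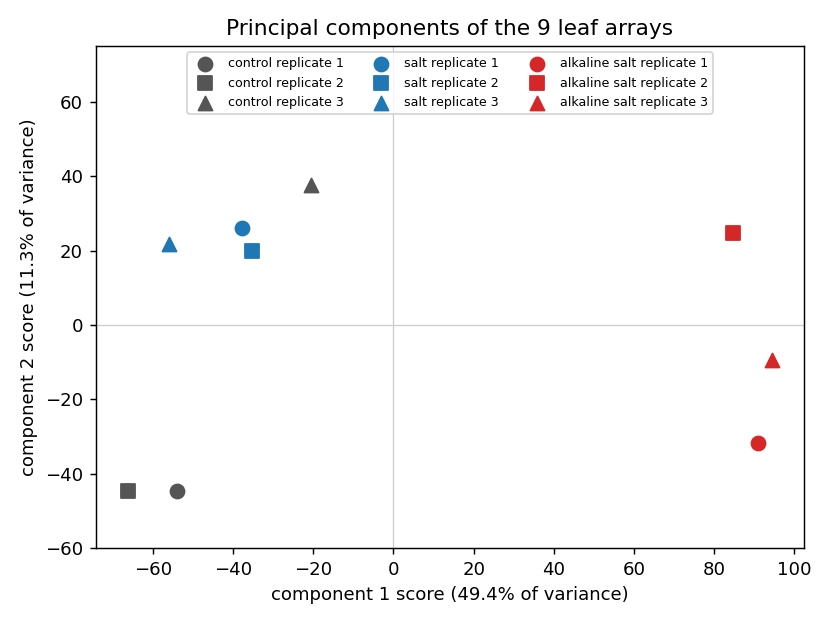
Scores of the 9 leaf arrays on the first component (horizontal axis, 49.4% of variance) and the second (vertical axis, 11.3%), with 1 point per plant, colour for the group and symbol shape for the replicate, which is also the slide. The alkaline salt plants lie at 84.7 or above on the first component and control replicate 3 lies at 37.7 on the second, beside the salt plants.

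The first comparison asked how salt with bicarbonate changed leaf transcripts relative to unstressed plants. In alkaline salt plants, 1425 probes were higher and 1755 lower than in controls, or 17.9% of the 17798 tested. Most changes were moderate: among called probes measured in both groups, the median change was 2.57-fold for those that rose and 2.44-fold for those that fell. Large changes were more often rises, with 411 probes at least 4-fold higher and 269 at least 4-fold lower, and 62 against 13 at 16-fold or more. These counts use bounds for the 215 risers that were not well above background in any control plant and the 132 fallers that were not in any alkaline salt plant.

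Among the probes with large rises was A_46_P212419, with a log2 fold change of 8.54 (SE 0.88, n = 3 per group, limma adjusted p = 0.000792). Its scaled log2 signal was −3.06 ± 2.11 (SD) in controls, −0.40 ± 0.52 in salt and 5.47 ± 0.41 in alkaline salt plants, and 1 of 3 control arrays, control replicate 3, was well above background. With signals raised to a common floor its log2 fold change was 7.09, and it was 7.63 without control replicate 2 and 9.69 without control replicate 3. A_46_P346705 rose by a log2 fold change of 8.35 (SE 0.94, limma adjusted p = 0.00107), with 1 of 3 control arrays above background, and by 6.86 with the common floor, 7.77 without control replicate 1 and 9.40 without control replicate 2. A_46_P143894 fell, with a log2 fold change of −8.18 (SE 1.23, limma adjusted p = 0.00351), from 6.37 ± 0.41 in controls to −1.80 ± 3.07 in alkaline salt plants, of which 2 were above background. Its log2 fold change was −6.50 without alkaline salt replicate 3, −9.51 without alkaline salt replicate 1 and −7.14 with the common floor. The other tested probe of its transcript was called in the same direction. A_46_P153170 fell by 5.95 on the log2 scale (SE 0.43, limma adjusted p = 0.000156) and was above background in 1 alkaline salt plant, with −5.48 at the common floor. Normexp background correction gave smaller log2 fold changes for these 4 probes, of 5.81, 5.63, −6.12 and −3.88 in the same order. The files do not pair these identifiers with genes.

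The groups did not overlap for 1421 of the risers and 1749 of the fallers, which by itself gives these probes 1 direction on all 3 slides. Calling favours such probes, so these counts are no separate support for the calls. Across all tested probes the groups did not overlap for 37.0%, where chance gives 10%. With the slide as a block, 1273 probes rose and 1628 fell. Of 1192 transcript identifiers with several tested probes, 251 had a called probe; in 245 of these all probes had the same sign, in 145 all were called in the same direction, and in 0 were probes called in opposite directions. The counts rest in part on single plants: without alkaline salt replicate 3 they were 782 and 811, without control replicate 1 the fallers were 966, and without control replicate 2 they were 998. Scaling to the array median gave 777 risers and 710 fallers.

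**Figure D2:**
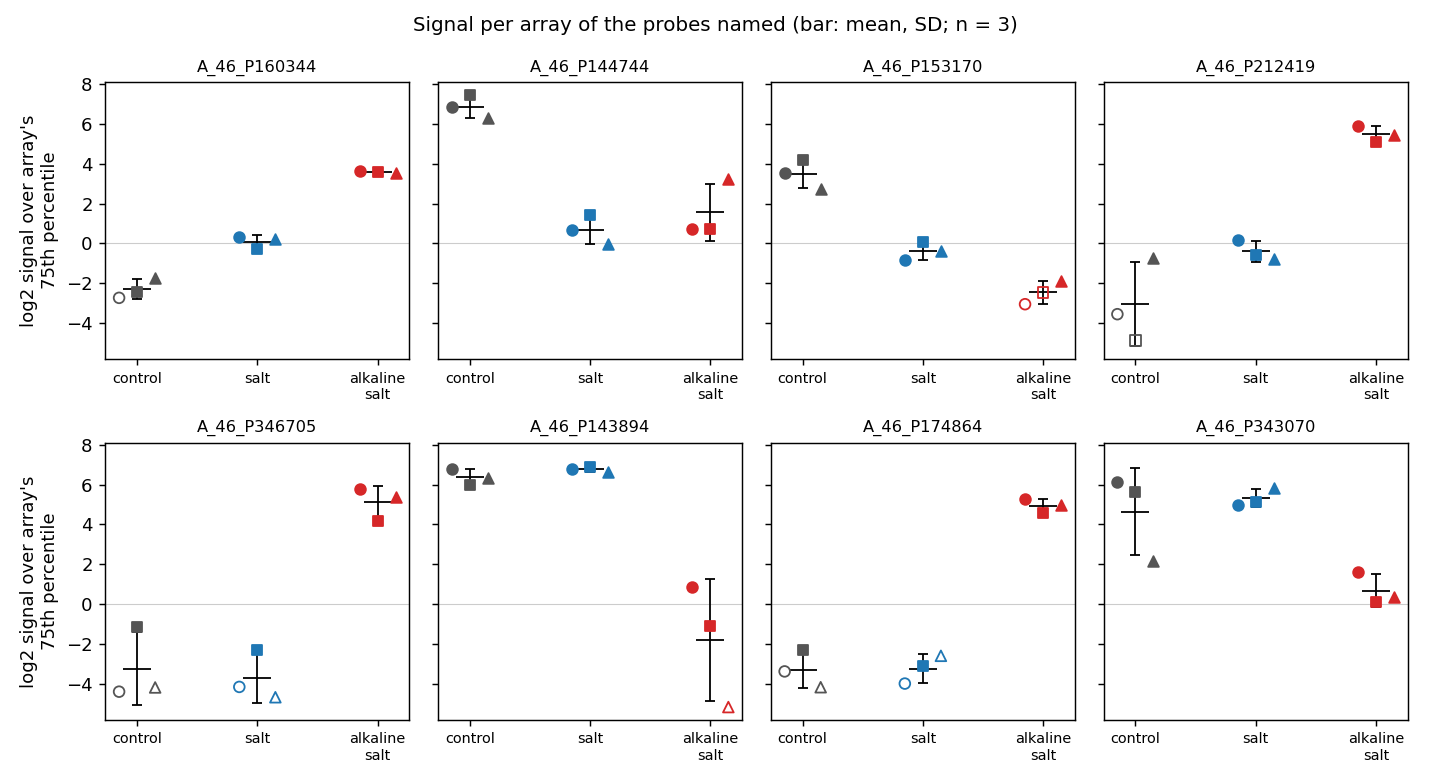
Log2 signal relative to the array's 75th percentile (vertical axis) of each named probe measured in both groups of its contrast, with 1 point per plant by group, open where the probe was not well above background, and a bar for the mean with its SD (n = 3). A_46_P212419 stood at 5.47 on average in alkaline salt plants and at −3.06 in controls, and A_46_P143894 at −1.80 and 6.37.

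The second comparison held NaCl constant and asked what the added bicarbonate changed. Alkaline salt plants had 1420 probes higher and 1288 lower than salt plants, or 15.2% of those tested. Of these, 470 were at least 4-fold higher and 229 at least 4-fold lower, and the median change of called probes measured in both groups was 2.72-fold up and 2.36-fold down. A_46_P346705 rose, with a log2 fold change of 8.81 (SE 0.94, limma adjusted p = 0.000975), from −3.70 ± 1.26 in salt plants to 5.11 ± 0.82; 1 salt array was above background, and the change was 7.17 with the common floor, 8.33 without salt replicate 3 and 9.52 without salt replicate 2. A_46_P174864 rose by 8.17 (SE 0.50, limma adjusted p = 6.9e-05), also with 1 salt array above background, and by 6.99 with the common floor. A_46_P143894 fell by 8.57 on the log2 scale (SE 1.23, limma adjusted p = 0.00329), with −6.89 without alkaline salt replicate 3 and −9.90 without alkaline salt replicate 1. A_46_P343070 fell by 4.63 (SE 0.94, limma adjusted p = 0.0145), from 5.31 ± 0.46 to 0.68 ± 0.82, above background on all 6 arrays. That call was lost without alkaline salt replicate 3 (limma adjusted p = 0.058) or salt replicate 3 (limma adjusted p = 0.053). With normexp the log2 fold changes of these 4 probes were 5.78, 5.58, −6.51 and −4.21.

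The groups did not overlap for 1419 of these risers and for all 1288 fallers, which calling again favours. Across all tested probes they did not overlap for 39.6%, where chance gives 10%. With the slide as a block, 1195 probes rose and 1161 fell. The share of calls that were rises was 52.4%, and 63.8% after scaling to the array median, which gave 820 risers and 465 fallers. Single plants mattered here too: the risers numbered 719 without alkaline salt replicate 3, 888 without alkaline salt replicate 1 and 866 without salt replicate 3, and the fallers 474 without alkaline salt replicate 3 and 600, 685 and 568 without salt replicates 1, 2 and 3.

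Both alkaline salt contrasts called largely the same probes. There were 1066 probes higher and 1051 lower in alkaline salt plants than in both other groups, and 0 were called in opposite directions. Independent lists of the same sizes would share 114 and 127. The contrasts share the alkaline salt arrays, and simulated data without effects, in which hardly any probe is called, gave at most 1 shared call. Neither reference shows what the shared arrays give where alkaline salt has an effect, so the overlap is no separate support for the calls. The total of 2117 was 959 without alkaline salt replicate 3, 1302 without salt replicate 1, 1255 without salt replicate 3, 943 after scaling to the array median and 852 with no filter on dim probes. A further 359 risers and 704 fallers were called against control alone, and 354 and 237 against salt alone; for these probes the difference between the contrasts is that between salt and control, tested next.

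The remaining comparison asked how 50 mM NaCl alone changed leaf transcripts. Few probes were called: 2 were higher and 4 lower in salt than in control plants. In simulated data for this comparison with 200 probes changed, the fit recovered 19.7% of 2-fold and 67.5% of 4-fold changes. Few calls therefore do not show that few transcripts changed by 2-fold, and they say more about changes of 4-fold. A_46_P160344 was 5.21-fold higher (log2 fold change 2.38, SE 0.28, n = 3 per group, limma adjusted p = 0.0479), at −2.29 ± 0.52 in controls, 0.09 ± 0.31 in salt and 3.59 ± 0.05 in alkaline salt plants; 2 of 3 control arrays were above background. With normexp its log2 fold change was 0.99 and not called (limma adjusted p = 0.0982). In the 75th percentile scaling it was also higher in alkaline salt than in salt plants, by 3.50 on the log2 scale (limma adjusted p = 0.000306). The other riser, A_46_P116804, was not well above background in any control plant and was higher by at least 2.04 on the log2 scale against each array's own lowest detected signal (limma adjusted p = 0.0133), by 1.70 against the common floor, and by 1.31 with normexp, where it was not called (limma adjusted p = 0.0979); it was not well above background in any alkaline salt plant either, so control and alkaline salt plants cannot be compared for it. A_46_P144744 fell by 6.19 on the log2 scale (SE 0.69, limma adjusted p = 0.0411), from 6.87 ± 0.57 to 0.68 ± 0.72, and the second probe of its transcript fell too. A_46_P153170 fell by 3.88 (SE 0.43, limma adjusted p = 0.0411; −3.14 with normexp), from 3.49 ± 0.73 in controls to −0.40 ± 0.45 in salt plants, and lay lower still in alkaline salt plants, at −2.46 ± 0.59.

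For all 6 probes the groups did not overlap. Across all tested probes, 1048 had an unadjusted p under 0.05 against 889.9 given by chance, and the groups did not overlap for 10.2% of probes, where chance gives 10%. With the slide, which is also the replicate number, as a block in limma, 0 probes were called (smallest adjusted p = 0.0592, 1060 probes at an unadjusted p under 0.05), while scaling to the array median gave 24 higher and 39 lower and quantile normalisation 5 and 8. The count of risers was 15 without control replicate 3 and 0 without control replicate 1, salt replicate 1 or salt replicate 3; the count of fallers was 15 without salt replicate 2, 2 without alkaline salt replicate 2 or 3, and 1 without control replicate 1, salt replicate 1 or alkaline salt replicate 1.

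Of the 6 probes called in salt, 5 were called in the same direction in alkaline salt against control, 1 higher and 4 lower. Among the 4 lower, A_46_P144744 and A_46_P231729 are probes of the same transcript, so the 4 are not independent. Independent lists would share 0.16 and 0.394, and simulated groups without effects against the same controls, which give hardly any calls, shared 0. A control group of 3 plants cannot be divided into parts of at least 2, so part of this overlap may come from the shared control arrays. The number shared was 26 after scaling to the array median, 10 after quantile normalisation or with the common floor, and 0 with the slide as a block. It was 15 without control replicate 3, 8 without salt replicate 2, 3 without alkaline salt replicate 3, 2 without alkaline salt replicate 2, and 1 without control replicate 1, salt replicate 1, salt replicate 3 or alkaline salt replicate 1.

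**Figure D3:**
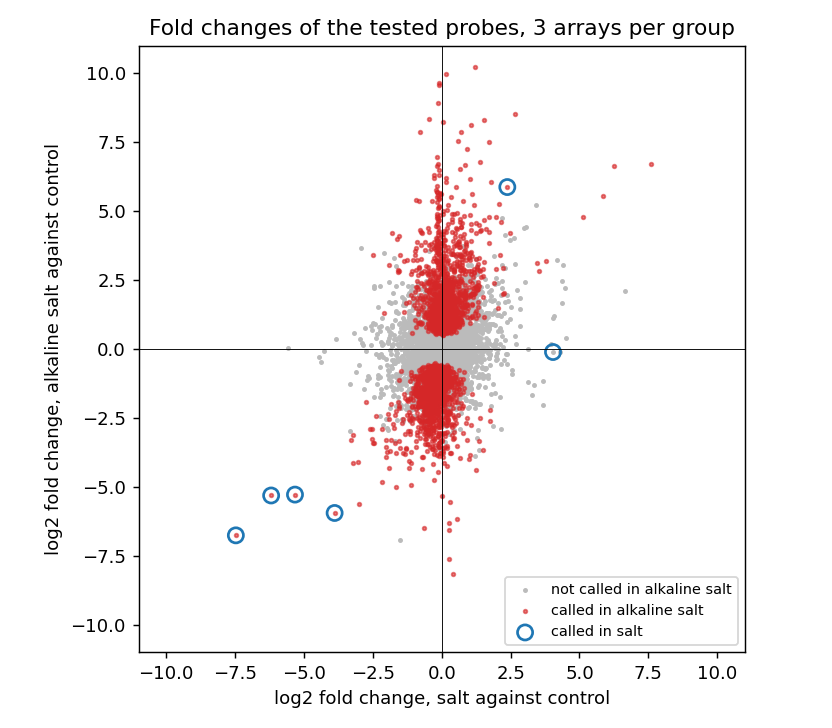
Log2 fold change of each tested probe in salt (horizontal axis) and alkaline salt (vertical axis) against the same 3 control plants, with 1 point per probe, red where called in alkaline salt and ringed where called in salt; fitted values are drawn also for probes below background in a group. The 3180 probes called in alkaline salt spread along the vertical axis, while 6 are ringed.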

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

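Scaling to the 75th percentile of probes detected on all arrays and a common floor at −2.06 were chosen after seeing the data, as was the count of probes called in both alkaline salt contrasts. The 4 counts of probes higher or lower in alkaline salt each stayed within 1.5 times their value under 14 of 16 alternatives, leaving single arrays out aside. The exceptions were median scaling and no filter on dim probes. Median scaling gave 777 higher and 710 lower against control, 820 and 465 against salt, and 943 called in both contrasts. It also shifted the median log2 fold change of salt against control from −0.04 to −0.12. Fewer than 50% of probes exceed background on most arrays, so the median is set by a probe near background. Median scaling hardly moved the fold changes of named probes but moved most of their p-values. In salt, A_46_P144744 had −6.27 (limma adjusted p = 3.97e-10) against −6.19 (limma adjusted p = 0.0411), while A_46_P160344 stayed at a limma adjusted p of 0.0483. In alkaline salt against control, A_46_P346705 had 8.34 (limma adjusted p = 2.6e-13) against 8.35 (limma adjusted p = 0.00107). For such probes the scaling changed the estimated spread, so these counts do not reflect fold changes alone. Without a filter 43603 probes were tested, with 794 and 681, 682 and 355 (65.8% higher), and 852 in both.

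The salt counts (2 higher, 4 lower, 5 shared with alkaline salt) moved under most alternatives. Quantile normalisation and the authors' value table each gave 5, 8 and 10, median scaling 24, 39 and 26, and the common floor 5, 9 and 10. The percentile over detected probes and the absent filter each gave 1, 1 and 1. Probes above background on all 9 arrays gave 0, 1 and 1. An unadjusted p with a 2-fold change gave 167, 249 and 170. Fitting only the 2 groups compared gave 5 higher and 2 shared, averaging per transcript identifier 1 and 3, and normexp 1 higher. Apart from the tested sets and the threshold, the cause was not tested.

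Arrays with the same replicate number share a slide and a scan. The sample titles do not say whether their plants were also grown or harvested together. Deviations of same-numbered arrays correlated between −0.145 and 0.290, with 1 of 9 pairs above 0.1, and 3 of 9 arrays correlated best with their own number. The replicate block gave 0 higher, 0 lower and 0 shared for salt in limma; against control it gave 1273 and 1628 in alkaline salt, sharing 2688 calls, and against salt 1195 and 1161, sharing 2155. The slide as a random block (correlation 0.0371) gave 2 and 4 for salt. The block moved no other count by more than 1.5 times.

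Leaving out single arrays gave 0 to 15 higher and 1 to 15 lower probes for salt, and 1 to 15 shared. For alkaline salt against control it gave 782 to 1761 higher and 811 to 1995 lower, and against salt 719 to 1597 and 474 to 1461. Between 959 and 2437 were called in both contrasts. The lowest alkaline salt counts came without alkaline salt replicate 3 and the highest without control replicate 3.

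No named probe changed direction under any alternative run for it. The 4 probes named in alkaline salt against control stayed past the threshold in all 21, as did 3 of those against salt, while A_46_P343070 missed it in 2 of 22. In salt, A_46_P160344 missed it in 12 of 21, A_46_P144744 in 9 of 22, A_46_P153170 in 11 of 21 and A_46_P116804 in 5 of 21. Tests of gene lists and all their alternatives were not run, as the files do not pair probes with genes. Signal over background limits the count of transcripts compared: 19712 of 43603 probes were above background on no array.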

Other observations

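The tests of the slide and of a wrong label for control replicate 3 were chosen after the arrays' positions were seen, and the other tests before their results.

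The probes detected also differed between the groups' arrays. There were 244 probes well above background in all 3 alkaline salt plants and in no control plant, and 110 the other way round. Against salt plants the counts were 144 and 106, and between salt and control plants 20 and 13. None of these counts was tested, and the lowest scaled log2 signal well above background ranged from −3.78 to −2.06 between arrays.

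Splitting the 6 arrays of a comparison in the 10 possible ways is too few for a share under 0.05. Alkaline salt against control called 3180 probes and the highest other split 2, so 1 split of 10 was as large, and alkaline salt against salt called 2708 against 2, again 1 of 10. For salt against control, 2 of the 10 splits called as many as the real 6; the other, which set control replicate 1 and salt replicates 1 and 3 against the rest, called 16. That split sets both slide 1 arrays against both slide 2 arrays and divides slide 3. With the slide as a block the real comparison called 0. Each slide held 1 array of every group, so for probes without missing values the block cannot change a fold change. Only the SE and the degrees of freedom can differ. The SE was 0.69 without and 0.77 with the block for A_46_P144744, and 0.28 and 0.27 for A_46_P160344. The block leaves fewer degrees of freedom (6.38 against 8.61), so the lost calls do not show the slide to be the source.

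Control replicate 3 lay nearer the alkaline salt plants than the other controls did, at 0.176 on an axis from salt (0) to alkaline salt (1) against −0.028 and −0.0919. Salt replicate 3, on the same slide, stood lower than the other salt plants (difference −0.157), but a single array does not exclude slide 3. Alkaline salt RNA mixed into the sample would give 1 share from all probes, and the estimate was 0.0228 from probes higher and 0.552 from probes lower in alkaline salt, a difference of 0.529 against an SD of 0.246 over the other 5 arrays; control replicate 2 differed by −0.517. A salt-treated plant under the control label should lie within 2 SDs of the salt plants' mean on this axis. Control replicate 3 lay 1.83 SDs above that mean, within the limit of 2. Control replicates 1 and 2 also lay within the range of the salt plants, −0.109 to 0.0867, so this place cannot tell the labels apart. Going with such a label, control replicate 3 lay at 0.999 on an axis from the other controls (0) to salt (1). The salt plants themselves spread over 1.47, 0.934 and 0.756 there. At the 19 probes called in salt without control replicate 3, its median position between the other controls (0) and salt (1) was 0.788. It was nearer salt at 12 of them and nearer control at 7. Control replicates 1 and 2 set the axis and these probes, so no other control plant was placed in this way. A control left out of such a choice can lie nearer salt for that reason alone. Against such a label stand the positions of control replicate 3 of at most 0.267 at the 4 of these probes called lower in salt. In 3 sets of 19 probes chosen without it and without 1 salt plant, it lay over 4 SDs off the salt mean towards control at 7, 13 and 9. The held-out salt plant lay so at 3, 9 and 3. Within each set, control replicate 3 thus lay so at more probes than the held-out salt plant, which goes against such a label. Its median gaps to the salt mean were 1.80, 7.35 and 3.26 SDs, against 0.97, 2.03 and 0.36 for the held-out salt plants. The rule chosen compared counts across sets: the lowest of control replicate 3 minus the highest of a salt plant was −2. By that rule, and with the values on the other side, the label stays open. The labels name no difference within the control group, and no biological explanation was tested.

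Whether salt and alkaline salt shared a response beyond the effect of the 3 shared control arrays stays open. The log2 fold changes of both contrasts had a covariance of 0.154 across probes (r = 0.282), above all 100 simulations of groups without effects, which averaged 0.102 (r = 0.499) and reached 0.114, so that the excess was 0.0512. With a different control plant for each contrast, the covariance was 0.0294 on average but ran from −0.163 to 0.220 over 6 pairs of control plants. Without control replicate 3 the covariance was 0.339, and with different control plants 0.192 on average and 0.165 at the lowest, but leaving out this plant was prompted by its place near the salt plants, and without control replicate 1 or 2 that average was −0.0329 or −0.0712. The simulations use the spread of all groups, and control plants varied more, so the range over pairs of control plants, which includes 0, keeps the question open.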
